A study of Homo sapiens with 4 samples.

How the data were processed

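HCC1143 is an established human cell line derived from a triple-negative breast carcinoma. Single cells of 4 groups were sequenced with the 10x Chromium platform, with 1 library per group: cells kept in DMSO, the solvent control, for 24 h or 72 h, and cells kept in 1 nM paclitaxel for 24 h or 72 h. Paclitaxel is a taxane that binds and stabilises microtubules. Per the labels' protocols, cells were plated in 6-well dishes and left to attach for 24 h before the drug or solvent was added, and RNA was captured by its poly(A) tail.

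The values deposited for each library are raw counts of unique molecular identifiers (UMIs) per gene symbol and cell barcode, with no normalization. Cell Ranger 2.0 and the genome build GRCh38 are named in the submitters' processing notes; how cells were selected is not given in the sources used here. In the deposited count tables every listed gene had a UMI in at least 1% of the cells of its table, with the fewest cells at 12, 8, 8 and 6 in the DMSO 24 h, paclitaxel 24 h, DMSO 72 h and paclitaxel 72 h libraries. A gene missing from 1 table is therefore not a measured 0. Such a gene was set to 11, 7, 7 or 5 UMIs in the respective library, an approximate bound that assumes about 1 UMI per cell, and counts under 3 were set to 3. The tables held 18131 genes in all, 15636 of them in every table, and no line without a gene name. Of the 227 gene symbols named by rule, 219 had exactly 1 locus in GENCODE release 29 on GRCh38, from which coordinates were taken.

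Barcodes with at least 500 detected genes and under 20% of UMIs from mitochondrially encoded (MT-) genes were kept. This left 3180 of 3194 barcodes; all 14 left out exceeded the MT- limit. UMIs were summed over the kept cells of a library and scaled to counts per 1000000 UMIs (CPM) of the summed total. Summed totals lay between 34850724 and 72024235 UMIs, so a count of 0 would have allowed at most 0.0417 to 0.0861 CPM. The ratio of 2 libraries is given as log2 of the CPM ratio with an exact (Clopper-Pearson) 95% interval for the ratio of 2 Poisson counts, and a CPM with an exact Poisson interval. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. All of these intervals cover counting error only. With 1 library per group no test across samples exists, no p-value was computed, and no difference has a replicate check: every comparison sets 1 library against 1 other library.

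Genes were counted as higher or lower when they differed by at least 1.5-fold, had a mean of at least 50 CPM over the 2 libraries and had an interval that excluded a ratio of 1. The choices of groups, thresholds, gene lists and most alternatives were made before the data were examined. The genes named are the 12 with the highest and the 12 with the lowest ratio at each time among genes with a mean of at least 50 CPM, without MT- and RPL/RPS genes. For the 2 DMSO libraries and for the change of the ratio between times the 6 highest and 6 lowest were taken. Added to these are up to 4 members of each list with the largest ratios, and 16 genes fixed in advance that include tubulins, keratins and cell cycle genes. Genes named outside this rule are marked where they appear, and 2 genes that the rule names are not reported here.

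Because scaling to the total shifts all genes when an abundant class changes, log2 ratios of genes are given minus the median log2 ratio of all genes with a mean of at least 50 CPM in that comparison and are called relative log2 ratios. For 36 fixed lists (26 pathways, 6 cell state marker sets and 4 sets for other cell types) the median log2 ratio over members with a mean of at least 10 CPM was compared with 10000 random lists of the same size matched on mean expression in 20 bins. The difference from the median of the random lists is called the relative median. List members with a mean of at least 10 CPM are called measured. Counts of genes and of list members past 1.5-fold use log2 ratios without either subtraction. A list with a percentile under 2.5 or over 97.5 is said to stand apart, as a description of these libraries; lists with under 5 members past the minimum have no median.

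Cell cycle phases were called with scanpy 1.11.5 from fixed S phase and G2/M phase lists after each cell had been thinned to 22400 UMIs. This left out 34, 43, 23 and 52 shallower cells in the DMSO 24 h, paclitaxel 24 h, DMSO 72 h and paclitaxel 72 h libraries. List UMIs per cell were counted in the same thinned cells. Cells called G1 are those with low scores on both lists. Values of these lists, and of lists that share their genes, are therefore shaped by that choice in cells called G1. All kept cells were clustered together (2000 variable genes without the S phase and G2/M phase lists, 30 principal components, 15 neighbours, Leiden resolution 0.5, leidenalg 0.10.2), with no batch correction. A cluster was named only if at least 3 fixed markers of 1 set were among its 10 leading genes. Scrublet marked 7, 4, 5 and 3 cells as doublets in the same library order, and these cells were kept.

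The alternatives were TMM scaling (edgeR 4.0.16 in R 4.3.3, applied to the summed UMI counts for its factors only), totals without MT-, RPL/RPS, MALAT1 and NEAT1 UMIs, all barcodes, a stricter cell filter (at least 2000 genes and under 10% MT-), removal of doublets, means of per-cell CPM, cells called G1 only, a mean of at least 20 CPM or no minimum, a fold of 2, list members with a mean of at least 50 CPM, other thinning depths and other cluster settings. Further alternatives chosen after the data were seen were the removal of cells under 2% MT-, the removal of genes missing from 1 table, other random control genes for the phase scores, and the DMSO 24 h library as the reference for paclitaxel at 72 h. The shuffled genes, the simulated unchanged library and the medians subtracted from both ratios, for the part of the way between the DMSO libraries, were added last. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

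The ratio and list steps were tested on simulated counts with 200 changed genes. These were independent Poisson counts from a single shared profile, with no spread between cells or libraries. The test therefore checks the computation and gives no error rate for the real libraries. Genes changed 1.2-fold could hardly be called at a cutoff of 1.5-fold. For the 24 h comparison with 2630 genes, all 67 genes changed 2-fold and all 66 changed 3-fold were called, 0 of 67 changed 1.2-fold and 0 of 2433 unchanged genes were called, and 94.5% of the intervals of unchanged genes held the true ratio. For the 72 h comparison with 2510 genes the calls were 67 of 67, 66 of 66, 0 of 67 and 0 of 2320. Of 400 random lists of unchanged genes, 23 (5.75%) stood apart at 24 h and 12 (3%) at 72 h. Near-identical copies share reads in such data: values of HLA genes, tubulins, HNRNPA1, NACA2 and other genes with close copies are uncertain in this respect.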

Results

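The series asks how HCC1143 breast cancer cells respond to a low dose of paclitaxel over time, cell by cell. The 4 libraries held 1102 barcodes (DMSO 24 h), 778 (paclitaxel 24 h), 788 (DMSO 72 h) and 526 (paclitaxel 72 h), of which 1101, 776, 783 and 520 were kept. The tables summed to 72057374, 55541173, 49396553 and 34997421 UMIs. The kept cells had medians of 59378, 59670, 54864 and 57545 UMIs and of 7433, 7232, 6902 and 7147 detected genes. The median share of MT- UMIs lay between 6.55% and 7.78%. Ribosomal protein genes took a median of 27.0% of a cell's UMIs in DMSO at 24 h, 33.1% in paclitaxel at 24 h, 40.6% in DMSO at 72 h and 27.5% in paclitaxel at 72 h. Each group was 1 library, so each value below describes that library, without replicates.

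At 24 h, over all cells, interferon-induced, antigen presentation and inflammatory genes were higher in the paclitaxel library than in the DMSO library, though the interferon-stimulated list did not stand apart within every cluster. The S phase and G2/M phase lists had lower medians over all cells, by little and with few members past 1.5-fold, and not within every cluster. IFI6, an interferon-induced mitochondrial protein gene, was at 199 CPM with paclitaxel and 37.1 CPM with DMSO, a relative log2 ratio of 2.57. ISG15, which encodes a ubiquitin-like protein induced by interferon, was at 579 against 192 CPM (1.73, 95% interval 1.70 to 1.76). HIST1H4C, a replication-dependent histone H4 gene, was at 381 CPM with paclitaxel against 1093 CPM with DMSO, a relative log2 ratio of -1.38 (-1.40 to -1.36). Without subtraction of the median its log2 ratio was -1.52, and it was -0.57 in cells called G1 and -1.52 and -1.10 within clusters 1 and 5. RNA was captured by its poly(A) tail, so histone counts do not measure histone RNA without such a tail. Tubulin genes, which encode the target of the drug, were close to the median of all genes in the whole libraries.

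The other genes with the highest ratios at 24 h were MGP (an inhibitor of calcification, relative log2 ratio 2.13), MMP7 (a matrix metalloproteinase, 1.83), C15orf48 (1.69), TSTD1 (1.56), the chemokine gene CXCL8 (1.53), the tight junction gene CLDN1 (1.44), the acute phase gene SAA1 (1.40), GLTSCR2 (1.40), CTGF (1.37) and the basal keratin gene KRT15 (1.33). The lowest after HIST1H4C were the cell cycle transcription factor gene MYBL2 (-0.98), ID3 (-0.93), SNRNP25 (-0.82), HIST1H1C (-0.80), the receptor tyrosine kinase gene AXL (-0.80), C12orf75 (-0.80), PIF1 (-0.78), NETO2 (-0.76), BOLA3 (-0.75), GTF3A (-0.75) and FOXM1 (-0.73). Without subtraction of the median the log2 ratio of KRT15 was 1.18, but only 0.36 in cells called G1 and 0.37 and 0.08 within clusters 1 and 5. PIF1 (-0.30) and NETO2 (-0.58) also fell under 1.5-fold in cells called G1. On GRCh38, IFI6 lies on chromosome 1 from 27666061 to 27672218, ISG15 on chromosome 1 from 1001138 to 1014540, and HIST1H4C on chromosome 6 from 26103876 to 26104310.

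**Figure D1:**
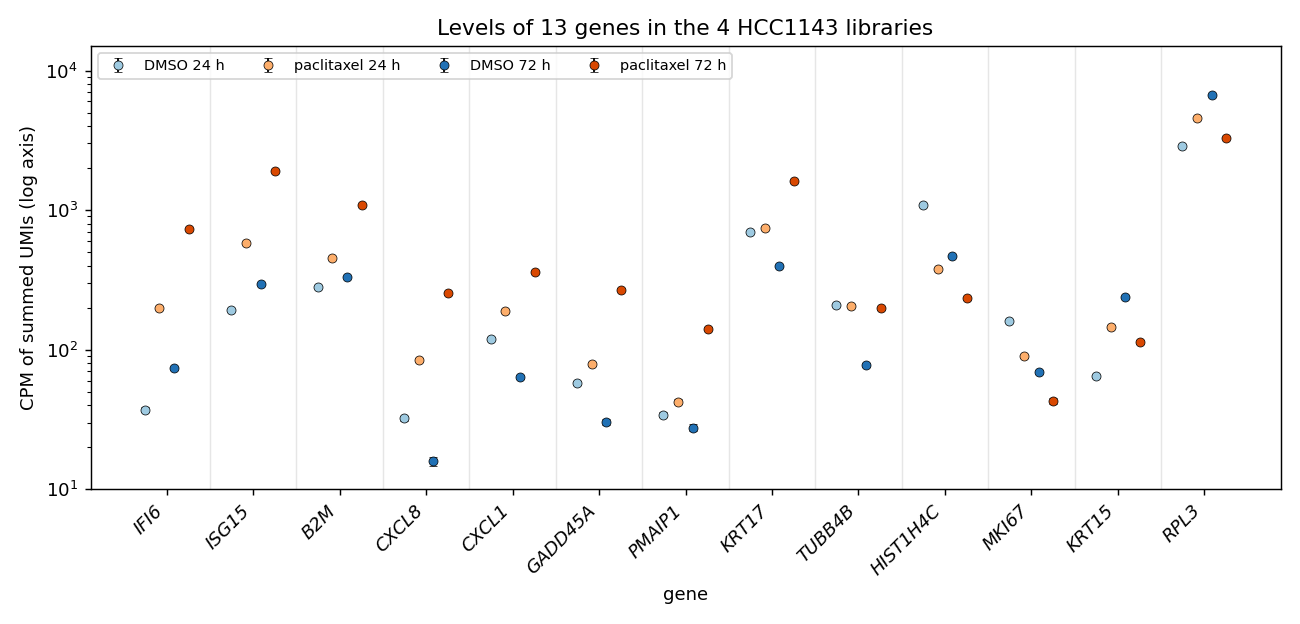
CPM of summed UMIs (log axis) of 13 genes in each of the 4 libraries; points are library values and bars are exact Poisson 95% intervals, mostly smaller than the points. IFI6 lies at 37.1 and 199 CPM at 24 h and at 73.3 and 736 CPM at 72 h in DMSO and paclitaxel, while KRT15 and RPL3 are higher with paclitaxel at 24 h and lower at 72 h.

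Of the interferon-stimulated genes, 12 of 16 measured members were at least 1.5-fold higher with paclitaxel at 24 h and 0 were lower, with a relative median of 0.98 (percentile 100 of random lists). Within cluster 1 the list did not stand apart (0.11, 2 of 12 higher), and within cluster 5 it stood apart at 0.30 with 1 of 11 higher. These clusters held 125 and 115 of the 776 paclitaxel 24 h cells, so they do not speak for the others. IFITM3, which restricts the entry of viruses, had a relative log2 ratio of 0.87. In the smaller set of interferon markers, all 3 measured members were higher. Of the genes of MHC class I presentation, 6 of 11 were at least 1.5-fold higher (relative median 0.73), among them HLA-C (0.86), B2M (0.83), HLA-B (0.81) and HLA-E (0.79). Within clusters 1 and 5 these genes stood apart by less, at 0.34 and 0.24, with 1 of 11 higher in each. Of the NF-kB and inflammatory genes, 8 of 14 were higher (relative median 0.86), with SOD2 at 1.03 and CXCL1 at 0.81 beside CXCL8 and SAA1. The immediate early genes had a relative median of 0.48, with 5 of 14 higher and CYR61 lower (-0.48). Within cluster 1 this list stood apart (0.34, 3 of 14 higher) and within cluster 5 it did not (0.11, 0 of 13 higher). JUNB (0.91) and MYC (0.83) were among the higher ones.

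S phase genes had a relative median of -0.24 at 24 h (9 of 40 at least 1.5-fold lower, 0 higher). RRM2, a subunit of ribonucleotide reductase, and HELLS were both at -0.56, CLSPN at -0.51 and ATAD2 at -0.48. G2/M phase genes had a relative median of -0.16 (4 of 52 lower, 0 higher), with the proliferation marker MKI67 at -0.71, GTSE1 at -0.55, ANLN at -0.46 and TPX2 at -0.42. Within cluster 1 these lists were at -0.37 and -0.24, and within cluster 5 at 0.07 and 0.06, where neither stood apart. The G2/M list no longer stood apart with members of at least 50 CPM (-0.12). The 2 shorter cycling marker sets also stood apart over all cells, at -0.35 for S phase and -0.19 for G2/M, the latter not with the stricter cell filter (-0.17). TOP2A was at -0.34 and CCNB1 at 0.51. Spindle checkpoint and kinetochore genes did not stand apart (relative median -0.05, percentile 21.2). They did as lower in cells called G1 (-0.48) and with per-cell means (-0.20), and as higher within cluster 5 (0.16). They share members with the G2/M phase list used to call G1, so the value in those cells cannot show a direction. The replication-dependent histones had a relative median of -0.82 over only 5 measured members of 15 listed, 3 lower and 1 higher. This value was 0.23 in cells called G1 and -0.02 with every cell weighted alike. Within cluster 1 it was -0.78 and stood apart.

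Luminal markers were the other group with a large difference at 24 h: 9 of 17 were at least 1.5-fold higher (relative median 0.74), led by the protease inhibitor gene SLPI (1.32), MUC1 (0.93), KRT19 (0.80) and CLDN4 (0.78). Squamous and cornified differentiation genes had a relative median of 0.50, with S100P at 0.85 and KRT6B at 0.70. Breast stem and progenitor markers had a relative median of 0.33, with NOTCH3 at 0.75 and SOX9 at 0.66. Within clusters 1 and 5 the stem and progenitor list did not stand apart (0.05 and -0.23), and squamous genes were at 0.44 and -0.12. Ribosomal protein genes stood apart at 0.47, with RPL10A at 1.02 and RPL3 at 0.81, but not within clusters 1 and 5 (0.03 and 0.01). Cholesterol biosynthesis (0.24), the unfolded protein and integrated stress response (0.20) and the proteasome (0.15) also stood apart, by less; in cells called G1 cholesterol biosynthesis and the proteasome turned direction (-0.026 and -0.042). The stress response list no longer stood apart in those cells (0.12), with per-cell means (0.14) or with members of at least 50 CPM (0.14), nor did the proteasome without doublets (0.15) or with per-cell means (0.13). Within clusters 1 and 5, however, both stood apart as higher, the stress response list at 0.48 and 0.31 and the proteasome at 0.32 and 0.48. Among their members, HMGCS1 was at 0.51, CEBPB at 0.78 and PSMA2 at 0.52.

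The remaining lists with a median did not stand apart at 24 h. Tubulins had a relative median of 0.09 (1 of 10 higher), with TUBB at -0.05, TUBA1B at -0.01, TUBB6 at 0.03, TUBB4B at 0.12, TUBB2A at 0.30 and TUBB3 at 0.63. Within the 2 clusters compared at 24 h, however, tubulins stood apart as higher with paclitaxel, at 0.48 (cluster 1, 4 of 10 higher) and 0.42 (cluster 5, 2 of 11 higher). The microtubule-associated proteins were at -0.03, p53 targets at 0.11, apoptosis-promoting genes at 0.09 and apoptosis-opposing genes at 0.04. Of these, CDKN1A was at 0.01, MDM2 at 0.01, GADD45A at 0.59, CFLAR at 0.77 and MCL1 at 0.45. Heat shock proteins were at 0.19, basal markers at 0.16, mesenchymal markers at 0.14, extracellular matrix genes at 0.08 and hypoxia and glycolysis genes at 0.06. Within clusters 1 and 5 basal markers stood apart on opposite sides (0.37 and -0.30), hypoxia and glycolysis genes stood apart as higher in both (0.23 and 0.19), and heat shock proteins did in cluster 5 alone (0.24). Apoptosis-promoting genes stood apart as higher in cluster 1 (0.23) but not in cluster 5 (0.18). Metallothioneins (0.00), mitochondrially encoded genes (-0.02), drug efflux and detoxification genes (-0.02) and nuclear oxidative phosphorylation genes (-0.07) were closest to 0 or below it, but metallothioneins were at -0.82 in cells called G1, and mitochondrially encoded genes stood apart as lower within clusters 1 and 5 (-0.33 and -0.51). KRT5 (-0.03), KRT14 (0.16), VIM (0.64) and CD44 (0.23) complete the genes fixed in advance, except ABCB1, the gene of the P-glycoprotein drug pump, which was in none of the 4 tables.

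Among 2633 genes, 111 were at least 1.5-fold higher and 116 lower with paclitaxel at 24 h, and the median log2 ratio of all of them was -0.14. The split depended on scaling: it was 161 to 61 with TMM factors and 166 to 56 with totals that leave out ribosomal and mitochondrial genes. It tipped the other way, to 125 to 195, with the mean of per-cell CPM.

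At 72 h, the paclitaxel library had far higher levels of inflammatory, interferon-induced and stress genes than the DMSO library. CXCL8, a chemokine that attracts neutrophils, was at 253 CPM with paclitaxel and 15.9 CPM with DMSO, a relative log2 ratio of 3.67 (3.57 to 3.78). IFI6 was at 736 against 73.3 CPM, a relative log2 ratio of 3.01 (2.96 to 3.06). GADD45A, a growth arrest and DNA damage gene, was at 269 against 30.2 CPM (2.84, 2.76 to 2.92). Tubulin genes were higher than in DMSO at the same time, and the S phase and G2/M phase lists were lower relative to the other genes over all cells, though not within every cluster.

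The next highest ratios at 72 h were those of ISG15 (relative log2 ratio 2.37), CXCL1 (2.17), the amino acid transporter subunit gene SLC3A2 (2.16), PMAIP1 (2.03), which encodes the pro-apoptotic protein NOXA, GADD45B (1.83), the non-coding RP11-54H7.4 (1.81), the autophagy gene MAP1LC3B (1.75), C5orf46 (1.75) and the keratin gene KRT17 (1.70). The lowest were LINC01297.1 (-2.36), ZNF90 (-1.65), HNRNPA1 (-1.49), KIAA0101 (-1.39), KRT15 (-1.38), HIST1H4C (-1.33), EIF4B (-1.29), TNS3 (-1.19), NACA2 (-1.19), FARP1 (-1.17), SLC25A6 (-1.17) and QARS (-1.16). Against DMSO at 24 h, 6 of these 12 turned direction: the log2 ratio was 0.48 for ZNF90, 0.83 for KRT15, 0.49 for EIF4B, 0.78 for NACA2, 0.48 for SLC25A6 and 0.65 for QARS. HNRNPA1 (-0.12), FARP1 (-0.13) and TNS3 (-0.58) kept their side but fell under 1.5-fold. Among the highest genes C5orf46 (0.53) did so too. HNRNPA1 and NACA2 share sequence with near-identical copies, so their counts are uncertain. On GRCh38, CXCL8 lies on chromosome 4 from 73740506 to 73743716 and GADD45A on chromosome 1 from 67685061 to 67688338.

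Counts of list members at 72 h are not relative to the median of all genes, and 702 of 2520 genes passed 1.5-fold as higher. Of the interferon-stimulated genes, 27 of 29 measured members were at least 1.5-fold higher at 72 h and 0 were lower (relative median 1.41, percentile 100), including BST2 (1.40). All 9 measured interferon markers were higher, with a relative median of 3.26. MHC class I presentation genes were higher in 11 of 12 cases (relative median 1.10), among them B2M at 1095 against 334 CPM (1.39), HLA-B (1.16) and HLA-C (1.14). NF-kB and inflammatory genes were higher in 15 of 17 cases (relative median 1.06), with SAA1 at 1.56 and SOD2 at 1.38. Immediate early genes had a relative median of 0.70 (13 of 16 higher), with KLF6 at 0.73, JUN at 0.60 and IER3 at 0.54. In this comparison the low DMSO level adds to 2 of these ratios: CXCL8 and CXCL1 were at 32.2 and 120 CPM in DMSO at 24 h and at 15.9 and 63.7 CPM in DMSO at 72 h.

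Stress and death genes followed. Of the unfolded protein and integrated stress response genes, 18 of 22 were at least 1.5-fold higher (relative median 0.86), including the phosphatase regulator gene PPP1R15A (1.58), the chaperone gene HSPA5 (1.12), XBP1 (1.11) and DDIT4 (0.93). Apoptosis-promoting genes were higher in 11 of 15 cases (relative median 0.59), with CYCS at 0.63, BIK at 0.56 and BAD at 0.27 beside PMAIP1. With members of at least 50 CPM this list no longer stood apart (0.38). Within clusters 2 and 3 it stood apart, at 0.33 and 0.27. Apoptosis-opposing genes lay just under the limit (0.36, percentile 97.2), with BIRC2 at 0.77 and BIRC3 and CFLAR both at 0.56. Among p53 targets 9 of 18 were higher (0.27), led by GADD45A and by the cyclin-dependent kinase inhibitor gene CDKN1A (109 against 42.9 CPM, 1.03), while BAX was at -0.37. The p53 list no longer stood apart without cells under 2% MT- (0.22), nor within clusters 2 and 3. Heat shock proteins had a relative median of 0.46, with HSPB1 at 1.09 and DNAJA1 at 0.92. The proteasome had one of 0.45 (22 of 28 higher), with PSMC4 at 1.19 and PSMB3 at 1.05. Drug efflux and detoxification genes were at 0.56, with NQO1 at 0.63 and GSTP1 at 0.03. Within clusters 2 and 3 heat shock proteins (0.13 and 0.21) and drug efflux genes (0.20 and 0.12) did not stand apart, while the proteasome did (0.16 and 0.21). Against DMSO at 24 h the proteasome (0.16, 2 higher and 2 lower), heat shock proteins (0.26) and drug efflux genes (0.07) no longer stood apart. The stress response list (0.47, 10 of 22 higher and 2 lower), apoptosis-promoting genes (0.45) and p53 targets (0.35) still did. The proteasome genes summed to 3999, 3873, 2322 and 3747 CPM in DMSO 24 h, paclitaxel 24 h, DMSO 72 h and paclitaxel 72 h, so the DMSO 72 h library was the low one.

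Tubulins had a relative median of 0.71 at 72 h, with 10 of 11 measured members at least 1.5-fold higher. That count depends on scaling: with TMM factors the log2 ratios of TUBA1B (0.54) and TUBB6 (0.37) fell under 1.5-fold. The largest relative log2 ratios were those of TUBB2A (2.54), TUBB3 (1.77, from 2.09 to 8.92 CPM), TUBA1A (1.41) and TUBB4B (1.03), followed by TUBA1B (0.51), TUBA1C (0.42), TUBB6 (0.33) and TUBB (0.19). The summed tubulin level was 2094 CPM in DMSO and 1955 CPM in paclitaxel at 24 h, and 1133 CPM in DMSO and 2023 CPM in paclitaxel at 72 h. Set against DMSO at 24 h the paclitaxel 72 h library had a tubulin relative median of 0.34, which no longer stood apart (percentile 96.5), and TUBA1B and TUBB4B had log2 ratios of -0.55 and -0.09. Within clusters 2 and 3, with only 47 and 32 paclitaxel cells, tubulins stood apart as higher than in DMSO at 72 h, at 0.64 (6 of 10 higher) and 1.11 (8 of 9 higher). Microtubule-associated proteins did not stand apart (-0.01), although MAP1B was at 0.58.

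Basal, luminal and squamous marker lists stood apart as higher at 72 h over all cells, while KRT15 was among the lowest genes. Within clusters 2 and 3 luminal markers stood apart (0.24 and 0.54), squamous genes did not (-0.10 and 0.14), and basal markers did in cluster 2 only (0.33 and 0.15). Basal markers had a relative median of 0.41 (8 of 14 higher), with KRT17, KRT6A (1.51), KRT14 (1.27), KRT6B (0.94) and KRT5 (0.40). Luminal markers were at 0.58 (12 of 18 higher), with LCN2 at 1.33, WFDC2 at 1.24 and KRT8 at 0.91, while KRT19 was at -0.05. Squamous and cornified differentiation genes were at 0.36 (9 of 15 higher), with S100P at 1.22. Breast stem and progenitor markers were at -0.02: EPCAM was at 0.73 and NOTCH3 at -0.81. Extracellular matrix genes (0.16) and mesenchymal markers (0.25) did not stand apart, although PLAUR was at 1.64 and MMP7 at 0.72; VIM was at -0.29 and CD44 at 0.13.

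S phase genes had a relative median of -0.29 at 72 h, with 4 of 37 at least 1.5-fold higher and 2 lower and a median log2 ratio of -0.01, so they lay below the other genes and near their DMSO level. CDCA7 was at -1.15, HELLS at -1.01, RRM2 at -0.83 and SLBP at 0.41. Within cluster 2 the S phase list stood apart as higher with paclitaxel (0.16, 6 of 40 higher) and within cluster 3 it did not stand apart (-0.14). G2/M phase genes were at -0.37 (5 of 49 higher, 7 lower), with CENPF at -1.14, MKI67 at -1.02 and TOP2A at -0.93, while TUBB4B and CKS2 (0.62), both on the list, were higher. The G2/M value was -0.34 within cluster 2 and -0.04, not standing apart, within cluster 3. In cells called G1 it was 0.22, but those cells were picked by low scores of this same list, so this value cannot show a direction. The cycling marker sets had relative medians of -0.37 for S phase and for G2/M, and spindle checkpoint genes of -0.11 (percentile 18.0). The G2/M set no longer stood apart in cells called G1 (-0.19), where the same limit holds because it shares genes with that list. Within clusters 2 and 3 it was at -0.53 and -0.02, the latter not standing apart. The S phase set was at 0.18 and -0.24 there and stood apart in neither. The histone list was at 0.47 over 6 members, 3 higher and 2 lower; it did not stand apart in cells called G1 (0.21) and stood apart as lower within cluster 3 (-0.67). Ribosomal protein genes were at -0.61 (11 of 40 lower, 0 higher), with RPL3 at -1.35 and RPL10A at -1.28. Within clusters 2 and 3 these genes stood apart by less, at -0.34 (2 of 40 lower) and -0.17 (1 of 40 lower). Against DMSO at 24 h their relative median was 0.30, although their summed levels were nearly equal (169637 CPM in paclitaxel at 72 h and 166889 CPM in DMSO at 24 h). Hypoxia and glycolysis (0.15), nuclear oxidative phosphorylation (0.14), cholesterol biosynthesis (0.14), metallothioneins (-0.05) and mitochondrially encoded genes (-0.14) did not stand apart, with ENO1 at 0.45, SDHB at 0.63, INSIG1 at 0.90, MT2A at -0.15 and MT-CO3 at -0.73.

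**Figure D2:**
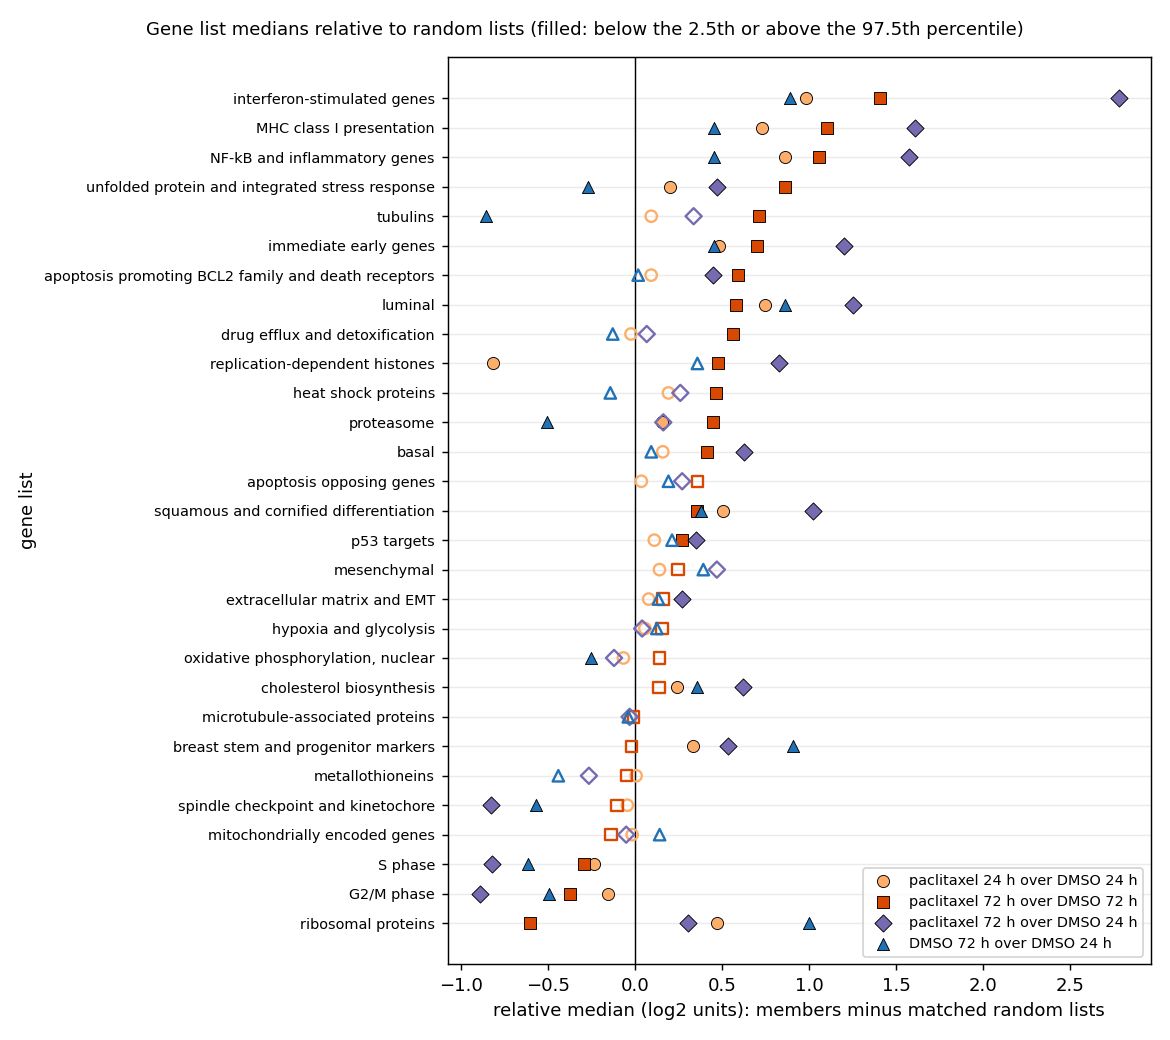
Relative medians (log2 units) of gene lists in 4 comparisons of libraries; filled symbols lie outside the central 95% of matched random lists. Interferon-stimulated genes lie at 0.98 and 1.41 with paclitaxel at 24 h and 72 h, while ribosomal proteins lie at 0.47 and -0.61 and tubulins at 0.09 and 0.71.

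Among 2520 genes, 702 were at least 1.5-fold higher and 69 lower with paclitaxel at 72 h, with a median log2 ratio of 0.32 over all of them; the split was 286 to 230 with TMM factors, 285 to 232 with totals that leave out ribosomal and mitochondrial genes, and 385 to 408 against DMSO at 24 h. Of 694 genes higher than in DMSO at 72 h and considered in both comparisons, 239 were also higher than in DMSO at 24 h (34.4%), and 19 of 65 lower ones were lower than both. With TMM factors these were 128 of 284 (45.1%) and 82 of 219. With totals that leave out ribosomal and mitochondrial genes they were 155 of 283 (54.8%) and 63 of 221.

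The 2 DMSO libraries, a measure of how far untreated libraries lay apart in time and preparation, differed in proliferation and in ribosomal genes. Ribosomal protein genes were higher at 72 h (relative median 1.00, 24 of 40 at least 1.5-fold higher), for example RPL3 at 6717 against 2880 CPM. S phase genes (-0.62, 32 of 40 lower), G2/M phase genes (-0.49, 44 of 52 lower), spindle checkpoint genes (-0.57), tubulins (-0.86) and the proteasome (-0.51) were lower at 72 h. The highest relative log2 ratios were those of the chemokine gene CCL28 (2.95), MGP (2.40), NDRG1 (2.37), GABRP (2.36), KRT15 (2.30) and GLTSCR2 (2.24). The lowest were those of ODC1, the rate-limiting enzyme of polyamine synthesis (-1.51), EBNA1BP2 (-1.39), CYR61 (-1.23), AXL (-1.21), CLSPN (-1.19) and GPATCH4 (-1.18).

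Interferon-stimulated genes were also higher in DMSO at 72 h than at 24 h (relative median 0.89, 11 of 17 higher), with IFI6 at 73.3 against 37.1 CPM. Luminal markers (0.86), breast stem and progenitor markers (0.91), MHC class I presentation (0.45), NF-kB and inflammatory genes (0.45), immediate early genes (0.46), squamous genes (0.38) and cholesterol biosynthesis (0.35) stood apart on the same side. The unfolded protein and integrated stress response (-0.27) and nuclear oxidative phosphorylation (-0.25) stood apart on the other. In cells called G1 squamous genes turned direction (-0.0427) and immediate early genes (0.18) and cholesterol biosynthesis (0.19) no longer stood apart. With members of at least 50 CPM tubulins (-0.48), cholesterol biosynthesis (0.35), squamous genes (0.26), NF-kB genes (0.17) and oxidative phosphorylation (-0.12) did not stand apart. Among 2470 genes, 171 were at least 1.5-fold higher and 876 lower at 72 h, with a median log2 ratio of -0.41. The split was 235 to 613 with TMM factors and 314 to 379 without ribosomal and mitochondrial genes in the totals.

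The paclitaxel 24 h library lay part of the way from DMSO at 24 h to DMSO at 72 h. Across 2440 genes the log2 ratios of paclitaxel 24 h and of DMSO 72 h, both over DMSO 24 h, had a Pearson correlation of 0.75 and a Spearman correlation of 0.69; genes are not independent replicates. The covariance was 0.143, against a median of 0.000291 in 100 simulations of unchanged groups that share the DMSO 24 h library (simulated correlation 0.42). Of the 103 genes higher in paclitaxel at 24 h, 73 were higher in DMSO at 72 h (6.67 for independent lists), and of 112 lower genes 105 were lower (40.2). Part of this excess may come from the shared library, whose cells were not split between the ratios. Such a split would still share that culture and library. Among 270 genes at least 2-fold apart between the DMSO libraries, 225 of them lower at 72 h, 94.8% had a paclitaxel 24 h ratio on the same side, and the median part of the log2 difference reached was 42.3%. These values were 61.5% and 9.40% with genes shuffled, and 51.2% and 0.0532% with a simulated unchanged paclitaxel library. Relative to the median of all genes, 179 of 181 genes (98.9%) were on the same side, with a part of 51.7%. The part is an average over cells: paclitaxel 24 h cells lay both in clusters with mostly DMSO 24 h cells (1 and 5) and in clusters with mostly DMSO 72 h cells (2 and 3), so it does not separate a shift of each cell from a mix of states. KRT15, GLTSCR2, ODC1 and AXL lay between the DMSO libraries, and MGP was at the same level as in DMSO at 72 h (167 and 168 CPM). IFI6, ISG15 and CXCL8 did not: each was higher in paclitaxel at 24 h than in either DMSO library.

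**Figure D3:**
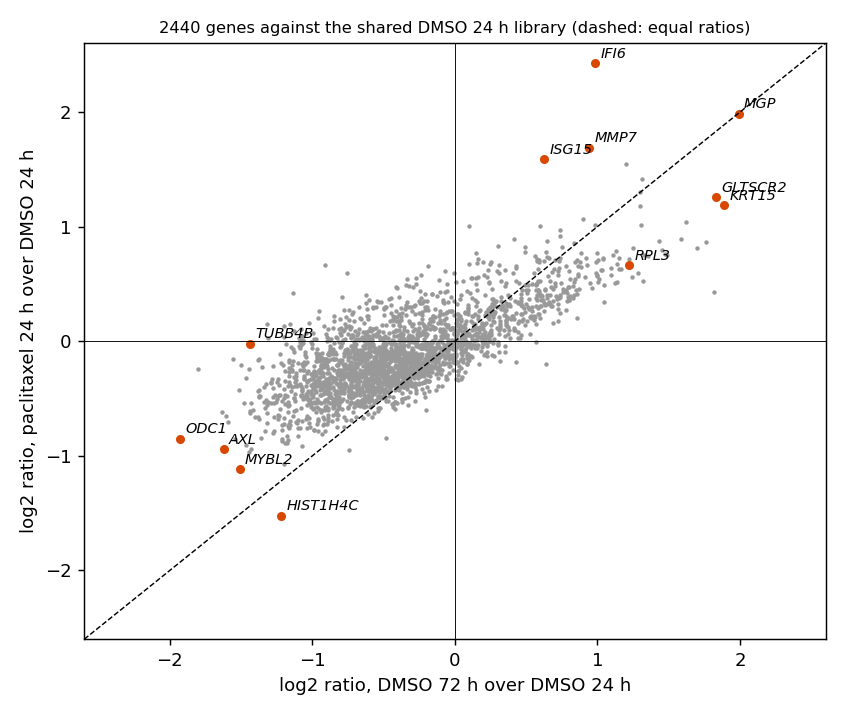
Log2 ratio of paclitaxel 24 h over DMSO 24 h (vertical axis) against that of DMSO 72 h over DMSO 24 h (horizontal axis) for 2440 genes, 1 point per gene, with a dashed line of equal ratios and 12 genes labelled. The points run upward with a slope below that of the dashed line (Pearson correlation 0.75), and IFI6, ISG15 and MMP7 lie above the line.

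Between 24 h and 72 h the paclitaxel ratio itself differed most for RP11-54H7.4 (log2 ratio -0.63 at 24 h and 2.13 at 72 h), GADD45A (0.45 and 3.16), CXCL8 (1.39 and 3.99), CYR61 (-0.62 and 1.82), C5orf46 (-0.34 and 2.07) and SLC3A2 (0.18 and 2.48). The opposite difference was largest for KRT15 (1.18 and -1.06), MGP (1.99 and -0.14), LINC01297.1 (0.00 and -2.04), GLTSCR2 (1.26 and -0.63), EIF4B (0.80 and -0.97) and ZNF90 (0.43 and -1.33). Each difference also holds the shift between the DMSO libraries. The log2 ratio of DMSO 72 h over 24 h was 1.89 for KRT15, 1.83 for GLTSCR2, 1.46 for EIF4B, -1.64 for CYR61 and -1.32 for RP11-54H7.4. Of 2324 genes considered at both times, 53 were at least 1.5-fold higher at both (29.5 for independent lists) and 5 lower at both (2.27). On opposite sides, 15 were higher at 24 h and lower at 72 h (3.10) and 6 lower at 24 h and higher at 72 h (21.5). The 5 lower at both were HELLS, HIST1H4C, KIAA0101, MKI67 and RABL6, of which RABL6 is named after its values were seen. This count was 10 with TMM factors (3.75 for independent lists) and 9 with totals without ribosomal and mitochondrial genes (3.41). It was 11 with per-cell means (5.00) and 2 in cells called G1 (4.45). Across genes the log2 ratios of the 2 times had a Pearson correlation of 0.19 and a Spearman correlation of 0.19.

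Called cell cycle phases differed between the libraries. G1 was called for 16.1% of cells in DMSO at 24 h (95% interval 14.0 to 18.5), 38.7% in paclitaxel at 24 h (35.2 to 42.4), 54.5% in DMSO at 72 h (50.9 to 58.1) and 66.5% in paclitaxel at 72 h (62.0 to 70.7). S phase shares were 26.0%, 20.1%, 13.9% and 7.05%, and G2/M shares 57.9%, 41.2%, 31.6% and 26.5%, in the same order. Without thinning the G1 shares were 16.9%, 40.5%, 54.9% and 68.7%. MKI67 was at 161, 89.4, 69.6 and 42.8 CPM. The G2/M phase list did not follow the order of the G1 shares: its sum was 5669, 4656, 2996 and 3301 CPM, and its median per thinned cell 105, 71, 36 and 46 UMIs, higher in paclitaxel than in DMSO at 72 h. At 0.5 of the depth, which also took in shallower cells, 8 of 12 shares moved outside their intervals and 4 did not. The G1 shares were then 18.8%, 45.5%, 59.6% and 69.8%, in the same order of libraries. Free RNA from other cells was not separated from a cell's own.

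**Figure D4:**
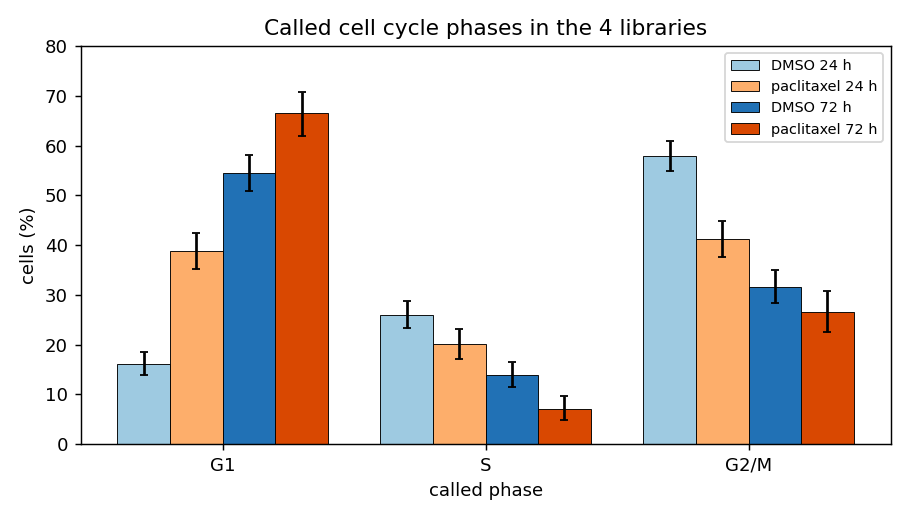
Share of cells (%) called G1, S or G2/M in each library after thinning to 22400 UMIs per cell; bars start at 0 and carry exact binomial 95% intervals. The G1 share is 16.1%, 38.7%, 54.5% and 66.5% in DMSO 24 h, paclitaxel 24 h, DMSO 72 h and paclitaxel 72 h.

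Counted per cell barcode, the higher interferon-stimulated level was spread over most paclitaxel cells. Free RNA from other cells was not separated, and its part in this spread is not known. At 22400 UMIs per cell, the median count of interferon-stimulated UMIs was 15 in DMSO and 33 in paclitaxel at 24 h, and 25 in DMSO and 91 in paclitaxel at 72 h. At 24 h 88.0% of paclitaxel cells lay above the DMSO median (85.4 to 90.3), and 63.3% above the 90th percentile of DMSO cells. At 72 h these shares were 97.2% (95.3 to 98.5) and 87.4%. For NF-kB and inflammatory genes 77.5% of paclitaxel cells lay above the DMSO median at 24 h and 90.6% at 72 h. For MHC class I presentation the shares were 84.0% and 94.0%.

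**Figure D5:**
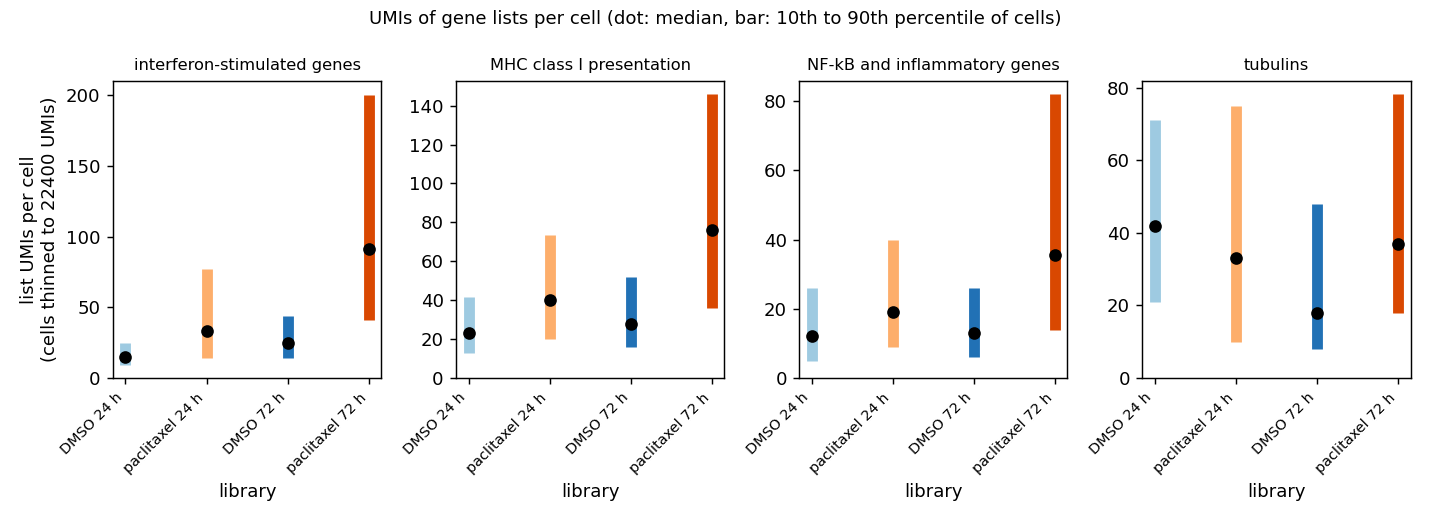
UMIs of 4 gene lists per cell in each library after thinning to 22400 UMIs; dots are medians over cells and bars run from the 10th to the 90th percentile of cells. Interferon-stimulated UMIs have medians of 15, 33, 25 and 91 in DMSO 24 h, paclitaxel 24 h, DMSO 72 h and paclitaxel 72 h.

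Clustering gave 7 clusters, of which 2 met the naming rule. Cluster 4 was interferon-like, with IFIT1, IFIT2, IFIT3, IFI27 and OAS1 among its 10 leading genes; 81.8% of its cells came from the paclitaxel 72 h library, so it may be that library and not a type. Cluster 5 was G2/M cycling-like, with AURKA, CCNB1, HMMR and PLK1. Within clusters that held at least 30 cells of both libraries, paclitaxel was set against DMSO. Most paclitaxel 72 h cells are outside this comparison, since they lay in cluster 4. Of the paclitaxel 24 h cells, 30.7% and 22.6% lay in clusters 2 and 3, which held too few DMSO 24 h cells to compare. Clusters were drawn from the same expression data and may sort cells by their response, so values within them do not stand for a whole library. At 72 h, in cluster 2 (47 paclitaxel and 342 DMSO cells) and cluster 3 (32 and 348), interferon-stimulated genes had relative medians of 1.23 and 1.58, and CXCL8 had log2 ratios of 1.77 and 2.69. At 24 h, in cluster 1 (125 and 622 cells) and cluster 5 (115 and 289), the interferon-stimulated relative median was 0.11 and 0.30, while CXCL8 had log2 ratios of 2.12 and 2.02. ISG15 was at 301 against 198 CPM in cluster 1.

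Markers of other cell types were low in every library. The 16 leukocyte markers summed to 8.47, 11.2, 11.4 and 28.2 CPM in DMSO 24 h, paclitaxel 24 h, DMSO 72 h and paclitaxel 72 h, with CD68 as the largest part (19.6 CPM in paclitaxel at 72 h and at most 6.29 CPM elsewhere), while PTPRC, the pan-leukocyte gene, had 10 UMIs in paclitaxel at 72 h and was not listed elsewhere. Fibroblast markers summed to 70.7, 50.8, 19.7 and 55.1 CPM, mostly TAGLN and COL1A1. Endothelial markers summed to 9.69, 12.1, 14.5 and 21.9 CPM. Of the erythroid markers only HBA1 and HBA2 were listed, at a sum of 0.319, 0.216 and 2.24 CPM in DMSO 24 h, paclitaxel 24 h and paclitaxel 72 h. Cells under 2% MT- made up 9.81% of the paclitaxel 72 h library and at most 1.40% of the others.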

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

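Of the tests below, those of depth and of the correlation in cells called G1 were fixed before their results were seen; the other tests were chosen only after. In 4 results the paclitaxel ratio lay on opposite sides at 24 h and 72 h, and in each the difference was not tested, since each group is 1 library. The ribosomal protein list had a relative median of 0.47 at 24 h and -0.61 at 72 h, a difference of -1.08. The replication-dependent histones had -0.82 and 0.47, a difference of 1.29, over only 5 and 6 members, and neither value was stable. The 24 h value was 0.23 in cells called G1, though -0.78 within cluster 1, where the list stood apart. The 72 h value no longer stood apart in cells called G1 (0.21) and was -0.67 within cluster 3. HIST1H4C itself was lower with paclitaxel at both times over all cells. In cells called G1 its log2 ratio, without subtraction of the median, was -0.57 at 24 h and -0.57 at 72 h. Both values were too small for the gene to be counted as lower in those cells. There were 15 genes higher at 24 h and lower at 72 h: RPL10, RPL10A, RPL13A, RPL3, RPL4, RPL5, RPS4X, EIF3E, EIF3F, EIF3L, EIF4B, GLTSCR2, KRT15, QARS and SLC25A6. There were 6 genes lower at 24 h and higher at 72 h: CYR61, DEF8, ODC1, RP11-1094M14.11, RP11-54H7.4 and SLIRP. In DMSO all 15 genes of the first group were higher at 72 h than at 24 h (log2 ratios from 0.99 to 1.89). All 6 of the second group were lower (from -1.02 to -1.93). The level of the DMSO 72 h library thus enters both groups, and its part was not tested. For independent lists 3.10 and 21.5 genes would be shared, so the second group is smaller than that. With TMM factors, and with totals without ribosomal and mitochondrial genes, the first group held 39 genes and the second 0. The second held 16 with per-cell means (39.3 for independent lists) and 24 in cells called G1 (38.7). Most of the genes in these 2 groups are named because the groups were seen, not by the fixed rule.

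Ribosomal protein genes, which serve protein synthesis, were higher with paclitaxel at 24 h and lower at 72 h. A different depth of the cells is argued against by a 72 h value of -0.64 in cells of 40000 to 80000 UMIs, and different shares of cells called G1 by -0.60 in those cells. The high level of these genes in the DMSO 72 h library fits: against DMSO at 24 h the paclitaxel 72 h library had a relative median of 0.30, so the reversal may come from the 72 h control. This value is relative to random lists and largely follows from values given above, so it is no independent test. The listed genes summed to nearly equal levels in DMSO at 24 h and paclitaxel at 72 h (166889 and 169637 CPM), against 241186 CPM in DMSO at 72 h. Open and untested are whether that control level belongs to 72 h of culture or to this 1 library and, since the list did not stand apart within clusters 1 and 5 at 24 h (0.03 and 0.01), whether the 24 h value reflects the mix of cell states. At 72 h the list stood apart by less within clusters 2 and 3 (-0.34 and -0.17), so the part of that mix in the 72 h value is open as well.

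The paclitaxel 24 h library lay part of the way from DMSO at 24 h to DMSO at 72 h. Counting error of the shared DMSO 24 h library is argued against by the covariance of 0.143, far above the highest simulated value of 0.000338, and different shares of cells called G1 by a correlation of 0.77 in cells called G1. Cells of the DMSO 72 h culture mixed in, as the whole cause, are argued against by clusters 2 and 3, where interferon-stimulated genes were higher in paclitaxel 24 h cells than in DMSO 72 h cells by relative medians of 0.52 and 0.60. A possible biological explanation is that paclitaxel slows growth and brings forward a state that untreated cultures reach later; this is a hypothesis found on the same data, which growth curves and untreated cultures sampled between 24 h and 72 h in replicate would test. Also open are a mix of cells in separate states in place of a shift of each cell, since the part of the way is an average, and a difference between library preparations, because each group has 1 library.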

How the results depend on the processing

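No paired analysis was possible because each group has 1 library, and no replicate could be left out. Values below are set against those in the report; the cause was not tested. Each relative median below ended the call that its list stood apart, except where it is marked as begun (a call only under the alternative) or turned (the other direction). The alternatives that remove cells under 2% MT-, remove genes missing from 1 table, use other control genes or use DMSO at 24 h as the reference were chosen after the data were seen.

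Counts are given as higher to lower at 24 h, at 72 h and between the DMSO libraries. They were 206 to 215, 1481 to 119 and 321 to 1594 with a mean of at least 20 CPM, 1170 to 862, 4964 to 506 and 1974 to 2949 with no minimum, and 19 to 3, 192 to 7 and 53 to 225 at a fold of 2. With TMM factors 61 genes were lower at 24 h, 286 higher and 230 lower at 72 h, 10 lower at both times, 39 higher at 24 h and lower at 72 h, and 0 the reverse. With totals without ribosomal and mitochondrial genes these were 56, 285, 232, 9, 39 and 0, and the DMSO libraries gave 314 to 379.

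With the mean of per-cell CPM 195 genes were lower at 24 h, 11 lower at both times and 16 lower at 24 h and higher at 72 h. Relative medians were then -0.20 (24 h) and -0.28 (72 h, both begun) for spindle checkpoint genes and, at 24 h, 0.14 for the unfolded protein response, 0.13 for the proteasome and -0.015 for histones; oxidative phosphorylation was at -0.20 between the DMSO libraries.

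In cells called G1 578 genes were lower in DMSO at 72 h, 2 lower at both times and 24 lower at 24 h and higher at 72 h. At 24 h relative medians were -0.48 for spindle checkpoint genes (begun), 0.12 for the unfolded protein response, -0.026 for cholesterol biosynthesis, -0.042 for the proteasome, -0.82 for metallothioneins and 0.23 for histones (all 4 turned), and 0.23 for extracellular matrix and 0.36 for mesenchymal markers (both begun). At 72 h they were 0.22 for G2/M phase genes (turned), 0.21 for histones and -0.19 for G2/M cycling markers. Between the DMSO libraries they were 0.18 for immediate early genes, 0.19 for cholesterol biosynthesis, -0.46 for drug efflux, -0.83 for metallothioneins and 0.62 for histones (all 3 begun), and -0.0427 for squamous genes and -0.39 for basal markers (both turned). The spindle checkpoint, G2/M phase and G2/M cycling values in these cells cannot show a direction, because G1 was called with many of the same genes.

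With DMSO at 24 h as the reference for paclitaxel at 72 h, 385 genes were higher and 408 lower. Relative medians were -0.83 for spindle checkpoint genes (begun), 0.34 for tubulins, 0.26 for heat shock proteins, 0.62 for cholesterol biosynthesis (begun), 0.16 for the proteasome, 0.30 for ribosomal proteins (turned), 0.066 for drug efflux, 0.27 for extracellular matrix (begun) and 0.53 for stem markers (turned). The log2 ratio turned direction for ZNF90 (0.48), KRT15 (0.83), EIF4B (0.49), NACA2 (0.78), SLC25A6 (0.48), QARS (0.65), CCNB1 (-0.17), TUBA1B (-0.55), TUBB4B (-0.086), TUBB6 (-0.29) and KRT5 (-0.16). It kept its side but fell under 1.5-fold for C5orf46 (0.53), HNRNPA1 (-0.12), TNS3 (-0.58) and FARP1 (-0.13).

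With list members at a mean of at least 50 CPM, relative medians at 24 h were -0.12 for G2/M phase genes, 0.14 for the unfolded protein response, 0.19 for cholesterol biosynthesis and 0.28 for extracellular matrix (begun). At 72 h they were 0.38 for apoptosis-promoting, 0.42 (begun) for apoptosis-opposing and 0.31 for squamous genes. Between the DMSO libraries they were -0.48 for tubulins, 0.17 for NF-kB genes, 0.35 for cholesterol biosynthesis, -0.12 for oxidative phosphorylation and 0.26 for squamous genes. Without doublets the proteasome was at 0.15 at 24 h. Without cells under 2% MT- p53 targets were at 0.22 and apoptosis-opposing genes at 0.36 (begun) at 72 h.

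With the stricter cell filter G2/M cycling markers were at -0.17 at 24 h and oxidative phosphorylation at -0.24 between the DMSO libraries. S and G2/M shares were then 30.6% and 53.1% in DMSO at 24 h and 16.95% and 26.6% in DMSO at 72 h, G2/M was 37.2% in paclitaxel at 24 h, and G1 and G2/M were 71.1% and 20.1% in paclitaxel at 72 h. At 0.5 of the thinning depth G1, S and G2/M were 18.8%, 14.5% and 66.7% in DMSO at 24 h, G1 and S were 45.5% and 11.1% in paclitaxel at 24 h and 59.6% and 8.05% in DMSO at 72 h, and S was 3.65% in paclitaxel at 72 h. Resolution 1.0 gave 14 clusters.

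Of 93 list medians, 75 were unchanged in cells called G1. Unchanged means that the call was kept, and a change of side counted only if either value stood apart. All 94 were unchanged under TMM factors and under totals without ribosomal genes, but this is no test. Both alternatives add the same constant to every log2 ratio of a comparison, so a relative median cannot move. Of 105 log2 ratios of named genes, 105 were unchanged with all barcodes, 96 with TMM factors and 93 in cells called G1. For genes a change of side counted only if either value passed 1.5-fold, so smaller ratios may have changed side.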

Other observations

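All tests in this part were chosen only after the results were seen, and the genes in the next 2 paragraphs were singled out after their values were seen; their log2 ratios are not relative to the median of all genes. Several interferon-induced genes too low for the named genes had large ratios. At 24 h IFIT1 had 301 UMIs with paclitaxel and 28 with DMSO (3.80), and OAS1 422 and 54 (3.34). At 72 h IFIT2 had 1549 and 69 UMIs (4.99), IFIT3 875 and 59 (4.39), IFI27 3180 and 255 (4.14), and IFI44L 1720 and 184 (3.72). The interferon lambda gene IFNL1 had 143 UMIs in paclitaxel at 72 h and was listed in no other table. The chemokine genes CCL5 (1104 and 45 UMIs, 5.12), CXCL10 (980 and 67, 4.37) and CCL20 (573 and 18, 5.49) were on the same side at 72 h.

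ATF3, DDIT3 and ASNS are genes of the integrated stress response, which lowers translation and induces amino acid synthesis under stress. ATF3 was at 19.8 against 15.1 CPM at 24 h and at 83.0 against 8.15 CPM at 72 h, DDIT3 had log2 ratios of 0.17 and 2.38, and ASNS of 0.66 and 2.02. PI3, an epithelial protease inhibitor gene, had log2 ratios of 1.58 at 24 h and 4.57 at 72 h. SQSTM1, an autophagy receptor gene, had 0.22 and 1.15.

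Interferon-stimulated genes were higher with paclitaxel at 24 h and 72 h. Leukocytes among the cells are argued against, since PTPRC had 10 UMIs while 97.2% of paclitaxel 72 h cells lay above the DMSO median. The share of cells alone does not decide this, because free RNA was not separated and could raise every cell. Cells under 2% MT- are argued against by a relative median of 1.47 without them at 72 h, and different shares of cells called G1 by a smaller value of the 2 times of 1.14 in those cells. An interferon response of the tumour cells themselves could explain the pattern, with IFNL1 as 1 candidate ligand, but this is a hypothesis found on the same data, which blocking interferon receptors or measuring IFNL1 protein would test. Differences between cultures or library preparations stay open, and at 24 h the list stood apart in only 1 of the 2 clusters compared. Those clusters held 125 and 115 of 776 paclitaxel 24 h cells. They were drawn from the same expression data, so they do not speak for the other cells.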
